A study of Mus musculus with 2 samples.

How the data were processed

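RNA was measured in muscle stem cells (MuSCs, the Pax7-expressing resident stem cells of skeletal muscle) of male mice of the C57BL/6 strain. There were 2 libraries, 1 from wild-type (WT) cells and 1 from double-knockout (dKO) cells, and the labels put each library in its group by genotype. The dKO genotype joins Pax7-CreER, a tamoxifen-inducible Cre recombinase under Pax7 control, with Esr2–/–, the homozygous loss of estrogen receptor beta, and with a Cre-deletable gene that, like a few other genes, is not reported here. Per the labels' protocols, mice were given tamoxifen by mouth (20 mg/mL) on 5 days in a row from 3 months of age. The sample titles carry the mark 6M, whose meaning is not given in the sources used here. Per the labels' protocols, limb muscle was digested with collagenase II and dispase, and cells were sorted by flow cytometry as negative for CD31, CD45 and Sca1 and positive for Vcam1. RNA was taken from these cells without culture.

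The deposited table holds whole-number read counts, 1 row per transcript, with an Entrez gene ID and a transcript length, per the file headers. Per the submitters' processing notes, TopHat2 2.0.9, bedtools, edgeR and the mm10 build were used, with no role or order stated. The counting rule, the annotation, the read type and the strand setting are not given in the sources used here, so reads of a gene and of an overlapping or antisense neighbour cannot be told apart, and reads of near-identical gene copies may have been divided between them. The table had 36780 rows for 24532 gene IDs, of which 24462 were matched to a symbol in a table of RefSeq genes on GRCm38, the assembly that mm10 names. IDs without a symbol took 0.314% of the WT and 0.401% of the dKO reads. Each row carried a gene ID, so all rows entered the library totals.

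The totals were 36636680 reads in the WT and 43699831 reads in the dKO library. A gene's value was that of its row with the highest mean share of the 2 libraries, a choice that concerns the 6494 gene IDs with several rows. The sum of a gene's rows was the alternative and is given beside a value wherever it moved a named gene across the 2-fold line or turned its sign. Library sizes were scaled with the trimmed mean of M values (TMM) in edgeR 4.0.16 (limma 3.58.1, R 4.3.3), which gave factors of 1.09 for WT and 0.920 for dKO. CPM values (counts per mega-read of library size) were computed with these scaled sizes, and the log2 ratio of a gene was that of dKO CPM + 1 over WT CPM + 1. Folds were ratios of CPM with no pseudocount, with an exact conditional binomial (Clopper-Pearson) 95% interval. A gene with 0 counts in 1 library was set against a floor of 3 counts in that library, which is 0.0753 CPM in WT and 0.0746 CPM in dKO. A fold given as "at least" is taken against this floor, and the 2-sided 95% interval reaches lower. Poisson intervals, binomial intervals and floors cover counting error only, since amplified reads are not independent molecules.

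No test between the groups was possible with 1 library each, so a rule of size was used. Genes with at least 10 counts in the higher library were called measured (14861 genes), and a measured gene with a log2 ratio of at least 1 in size was counted as 2-fold apart. For each gene list, the median log2 ratio of the measured members was placed among 10000 random lists of the same size drawn from like-expressed genes (20 bins of mean expression). This percentile describes where a list stands within these 2 libraries and is not a test of the genotype. The comparison, the size rule, the 35 lists, the named-gene rule and most alternatives were fixed before the data were examined. The rule named the targeted genes, the 12 genes with the highest and the 12 with the lowest log2 ratio among genes with at least 50 counts in the higher library, the 10 most abundant genes of each library, and up to 4 members per list with the largest log2 ratio among those 2-fold apart. Where a list had fewer than 2 such members, its 2 most abundant members were named. Symbols with no named function (Gm numbers, Rik clones and the like) were only counted. Other genes are named for the sort or chosen after their values were seen, and the text says so.

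Alternatives were median-ratio scaling, library totals alone, pseudocounts of 0.1 and 5, the sum of rows, no count floor or a floor of 100, a 1.5-fold or 4-fold rule, and the mean of list members. Chosen after seeing the data were genes with 1 row only, a 2-fold rule met by both the row and the sum, and the removal of a cubic trend on abundance, transcript length and GC content. GC content came from the GENCODE M21 transcripts and was known for 95.4% of the measured genes. The steps were tested on simulated counts for 14549 genes with the means and sizes of these libraries, of which 200 were changed. For dKO against WT, 86% of 100 genes changed by 2.5-fold and 95% of 100 genes changed by 4-fold were recovered, and 0 of 14349 unchanged genes were called. Of 200 simulated lists of 20 unchanged genes, 13 lay outside the 2.5 to 97.5 percentile range. The simulation holds counting error and no spread between animals. Counts were drawn per gene and not per transcript row, so no division of reads among rows or gene copies was simulated. The 0 calls therefore say nothing about false calls from that source. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.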

Results

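Gene expression was compared between freshly sorted muscle stem cells of a WT and a dKO male mouse group, with 1 RNA-seq library each. The comparison asks what the dKO genotype, which includes the loss of estrogen receptor beta, does to these cells, under a series title on sex hormones and muscle stem cells. The WT library held 36636680 and the dKO library 43699831 reads assigned to transcripts, and 14861 genes were measured. The 10 most abundant genes took 5.24% of the WT and 6.12% of the dKO reads, and 8222 gene IDs had 0 counts in both. With 1 library per group, no difference described here has a replicate check, and each statement compares these 2 libraries.

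Esr2, which encodes estrogen receptor beta (Entrez ID 13983, protein-coding, chromosome 12, 76120419 to 76177259 on GRCm38), was near the lower end of detection in both libraries. It had 71 counts in WT (95% Poisson interval 55.5 to 89.6) and 45 in dKO (32.8 to 60.2), or 1.78 and 1.12 CPM, with a dKO to WT ratio of 0.628 (0.423 to 0.925). The deleted part of Esr2 is not given in the sources used here, so counts in the rest of the gene check nothing about that label. Esr1, the gene of estrogen receptor alpha, named here after its value was seen, had 3582 and 3623 counts.

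The dKO library had less RNA of endothelial and immune marker genes and more of several cytokine, oxidative stress and myogenic genes. Of the cytokine, oxidative stress and myogenic lists, only the cytokine one had a median above the range of random lists. Endothelial markers had a median log2 ratio of −1.59 and immune cell markers one of −2.02. Higher in dKO were Fosl1 (4.90-fold, 4.71 to 5.10), an AP-1 subunit, Srxn1 (4.34-fold, 4.21 to 4.47), an antioxidant enzyme, and Myod1 (3.10-fold, 3.01 to 3.20), the master regulator of the myogenic lineage. Ribosomal protein genes had a median log2 ratio of 0.59, which was −0.02 once a trend on abundance, transcript length and GC content was removed. By the 2-fold rule, 455 measured genes (3.06%) were higher in dKO, 897 (6.04%) were lower and 13509 were neither. With library totals alone, 260 were higher and 1305 lower, so lower genes were 66.3% of those 2-fold apart under TMM and 83.4% under totals. With that trend removed, an alternative chosen after seeing the data, 515 were higher and 627 lower, which is 54.9% lower. By the sum of a gene's rows, 286 were higher and 640 lower. Uncharacterised symbols made up 27 of the higher and 26 of the lower genes. The median log2 ratio of all measured genes was −0.03, and it was −0.23 under library totals, a shift of −0.20 in that median. Of 34 gene lists with measured members, 12 had a median below and 6 a median above the middle 95% of random lists of like-expressed genes.

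**Figure D1:**
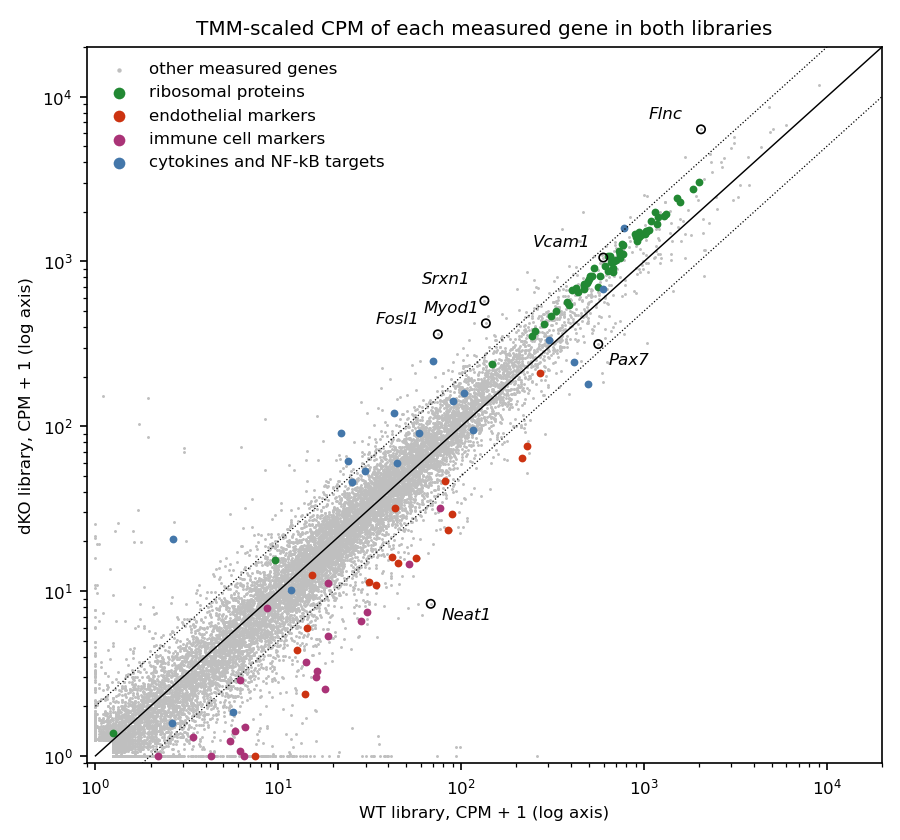
Each point is a measured gene, with CPM + 1 in the WT library on the x axis and in the dKO library on the y axis, both logarithmic; the solid line marks equal values and the dotted lines a 2-fold difference. Endothelial (red) and immune (purple) markers lie below the line, ribosomal protein genes (green) lie just above it, and Flnc had 2047 CPM in WT and 6329 CPM in dKO.

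Genes known to respond to sex steroids did not move together. Of 12 measured androgen-responsive genes, 2 were higher and 2 lower by 2-fold, with a median log2 ratio of 0.14 (percentile 41.5) that turned to −0.10 both under library totals and with the trend removed. Zbtb16, a zinc-finger transcription factor, was 3.44-fold lower (3.29 to 3.59), and Kcnk1, a potassium channel, was 2.45-fold lower (2.15 to 2.81). Odc1, the rate-limiting enzyme of polyamine synthesis, was 2.58-fold higher (2.56 to 2.60), with 66411 counts in WT and 172845 in dKO. Acsl3, a fatty acid activating enzyme, had a log2 ratio of 1.09 by its main row and 0.87 by the sum. Of the 12 measured estrogen-responsive genes, 1 (Myc, log2 ratio 1.30) was 2-fold higher and 0 lower, and the median of 0.09 (percentile 39.3) turned to −0.12 under library totals. Its abundant members Igfbp4 and Xbp1 had log2 ratios of 0.57 and 0.90.

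Glucocorticoid-responsive genes included 3 of 13 that were lower by 2-fold, and 0 were higher. These were Zbtb16, Tsc22d3 (the glucocorticoid-induced leucine zipper GILZ), 3.32-fold lower (3.10 to 3.54), and Fam107a, 2.73-fold lower (2.35 to 3.18). The list median was −0.01 (percentile 3.47), and it was 0.0039 with median-ratio scaling, −0.25 under library totals and −0.51 with the trend on abundance, length and GC content removed. Among 12 measured sex steroid receptors and steroid enzymes, 2 were lower by 2-fold, among them the membrane estrogen receptor gene Gper1 (log2 ratio −1.01, 170 and 65 counts), and 0 were higher. The median of that list was 0.01 (percentile 50.7), −0.22 under library totals and −0.09 with the trend removed.

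Muscle stem cell identity genes were mostly close in level, but stood below like-expressed genes as a group. Of 31 members, 1 was lower by 2-fold, 0 were higher and 19 were below 0, and the median log2 ratio of −0.07 lay at percentile 0.15 and was −0.37 with the trend removed. The member past 2-fold was Foxo3, a transcription factor of quiescence (2.30-fold lower, 2.16 to 2.45). Pax7, the defining transcription factor of these cells, had 22335 counts in WT and 12620 in dKO and was 1.79-fold lower (1.75 to 1.83). Foxo3 and Pax7 were chosen after their values were seen. The most abundant members were the syndecan Sdc4 (log2 ratio 0.70) and the dystroglycan gene Dag1 (−0.42). Notch pathway genes, whose signal holds stem cells quiescent, had a median of −0.16 (percentile 1.57), with 4 of 27 lower by 2-fold and 0 higher. Notch4 (−1.22), the ligand gene Jag2 (−1.19) and Hes6 (−1.04) were lower by both row and sum. Which cells their RNA came from was not tested, and endothelial markers were lower as well (median −1.59), so no change of Notch signal in stem cells can be read from them. Rbpj, the DNA-binding partner of Notch, was −1.51 by its main row but 0.28 by the sum of its rows.

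Myogenic commitment and differentiation genes had 4 of 23 members higher by 2-fold and 0 lower, with a median log2 ratio of 0.16 (percentile 95.3). Besides Myod1 (5396 counts in WT, 16886 in dKO), cardiac actin Actc1 was 3.41-fold higher (2.73 to 4.29) and the embryonic myosin light chain gene Myl4 2.90-fold higher (2.31 to 3.66). The main row of Mef2c had 0 counts in WT and 270 in dKO, at least 89.2-fold higher against the floor, yet the sum of its rows gave a log2 ratio of −0.46. Mature myofibre genes had a median of −0.28 (percentile 0.28), with 20 of 27 below 0, 1 higher by 2-fold and 0 lower. Their RNA may be carried over from fibres, which was not tested. The member higher by 2-fold, named after its value was seen, was the calcium release channel gene Ryr1 (log2 ratio 1.30). The abundant fibre genes Actn3 and Acta1 had values of −0.02 and −0.55. Cell cycle genes had 2 of 33 higher and 0 lower, with a median of 0.08 (percentile 94.1) that turned to −0.08 under library totals. Rrm1, a ribonucleotide reductase subunit, was 2.07-fold higher (1.96 to 2.18). The spindle gene Tpx2 was 0 against 199 counts by its main row (at least 65.7-fold higher) but had a log2 ratio of 0.75 by the sum.

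Immediate early genes, which respond within minutes to cell dissociation, were abundant in both libraries, and 3 of 26 were higher in dKO by 2-fold and 0 lower. Fosl1, Myc (2.48-fold, 2.39 to 2.57) and Ier5 (2.15-fold, 2.08 to 2.21) were higher, while the list median of 0.06 was low for such abundant genes (percentile 1.19) and became −0.18 under library totals and −0.36 with the trend removed. None of 15 heat shock genes was 2-fold apart, and the median of 0.38 (percentile 67.8) turned to −0.02 with the trend removed. Hspa8, a constitutive chaperone, had a log2 ratio of 0.87 and the inducible Hspa1b one of −0.37. Among 17 oxidative stress response genes, 4 were higher and 0 lower, with a median of 0.32 (percentile 85.3; 0.05 with the trend removed). With Srxn1 these were heme oxygenase Hmox1 (3.03-fold, 2.93 to 3.13), Txnrd1 (2.42-fold, 2.37 to 2.46; log2 ratio 0.98 by the sum) and Gclm (2.08-fold, 1.94 to 2.23), all known targets of the transcription factor Nrf2.

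Unfolded protein and integrated stress response genes had a median of 0.55 (percentile 99.7), with 15 of 17 above 0, and one of 0.21 with the trend on abundance, length and GC content removed. By 2-fold, 2 were higher and 0 lower. Sesn2, a stress-induced sestrin, was 2.99-fold higher (2.77 to 3.24) and Chac1, a glutathione-degrading enzyme, 2.25-fold higher (1.87 to 2.71). Of 21 p53 target and senescence genes, Sesn2 was higher and Trp53inp1 (log2 ratio −1.04) lower, with a median of 0.13 (percentile 69.7) that turned to −0.11 under library totals and −0.02 with the trend removed. Autophagy and FoxO target genes had 1 of 19 lower by 2-fold, the muscle ubiquitin ligase gene Trim63 (−1.11, named after its value was seen), and 0 higher. Their median was 0.18 (percentile 66.2) and −0.06 under library totals, and the autophagy adaptor gene Sqstm1 and the cathepsin gene Ctsl had log2 ratios of 0.80 and 0.18. Circadian clock genes had a median of 0.18 (percentile 75.8; −0.05 under library totals), with 1 of 16 higher and 1 lower. Cry1 was 2.56-fold higher (2.39 to 2.74), and Per3 was −1.09 by its main row but 0.01 by the sum.

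Cytokine and NF-κB target genes stood at or above each of the 10000 random lists of like-expressed genes, with a median log2 ratio of 0.62 (interval −0.21 to 1.03), which was 0.24 with the trend on abundance, length and GC content removed. Of 20 members, 6 were higher by 2-fold and 2 lower. The chemokine genes Cxcl5 (11.9-fold, 9.24 to 15.5; 66 and 792 counts) and Ccl11 (3.55-fold, 3.41 to 3.71) and the cytokine gene Lif (4.25-fold, 3.95 to 4.59) were higher. Il1b, the gene of a myeloid cytokine, was 5.52-fold lower (3.81 to 8.21). Named after its value was seen, Tnfaip3, a feedback inhibitor of NF-κB, was the other lower member (log2 ratio −1.45). Interferon response genes had a median of 0.49 (percentile 99.99; 0.24 with the trend removed), with 6 of 27 higher and 1 lower. Irf7, a transcription factor of the response, was 2.64-fold higher (2.27 to 3.08) and the guanylate-binding protein gene Gbp2 2.38-fold higher (log2 ratio 1.24), while the antiviral gene Rsad2 was 3.05-fold lower (2.36 to 3.99). Ifi47 had 84 and 763 counts and a log2 ratio of 2.68 by its main row, and one of 0.97 by the sum.

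Markers of cell types that the sort was set to exclude were lower in the dKO library. All 17 endothelial markers were below 0 and 13 were lower by 2-fold, among them Egfl7 (9.50-fold, 7.19 to 12.8; log2 ratio −1.62 by the sum), Ptprb (3.73-fold, 3.47 to 4.02) and the VEGF receptor gene Flt1 (3.73-fold, 3.41 to 4.09). The transcription factor gene Erg had 258 counts in WT and 0 in dKO in its main row, at least 86.8-fold lower, with a log2 ratio of −1.19 by the sum. Of 20 measured immune markers, all were below 0 and 18 were lower by 2-fold, with a median of −2.02. It became −2.07 when the 3 members with a count of 0 took their fold against the floor. That fold has no pseudocount, unlike the values of the other members, so the 2 medians are not on the same scale. The complement gene C1qb was 11.0-fold lower (8.47 to 14.5), Laptm5 7.50-fold lower (5.94 to 9.58) and the integrin gene Itgam at least 74.0-fold lower by its main row (220 and 0 counts) and 19.4-fold lower by the sum (12.3 to 32.6). Coro1a, with 205 and 3 counts, was 68.9-fold lower (23.3 to 337) by its main row and had a log2 ratio of −1.75 by the sum. Both medians lay below each of the 10000 random lists. The genes of the surface proteins used for the sort, named for that reason, followed the same pattern: Pecam1 (CD31) was 2.71-fold lower, Ptprc (CD45) 11.3-fold lower (191 and 17 counts) and Ly6a (Sca1) 7.59-fold lower, while Vcam1 was 1.77-fold higher (1.74 to 1.79).

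Other stromal cell types differed in the same direction but less. Fibro-adipogenic progenitor markers had a median of −0.48, with 7 of 20 lower by 2-fold and 0 higher. Ly6a, Mfap5 (3.85-fold, 3.32 to 4.48), Pi16 (3.96-fold, 3.31 to 4.77) and Dpp4 (3.03-fold, 2.62 to 3.52) were the 4 with the largest differences. Tendon cell markers had a median of −0.73, with 2 of 10 lower and 0 higher: Thbs4 (2.61-fold, 2.57 to 2.64) and the transcription factor gene Scx (2.22-fold, 1.94 to 2.55). Mural and smooth muscle markers had a median of −0.40 (percentile 0.04), with 3 of 13 lower and 0 higher, namely Kcnj8 (log2 ratio −2.27, and −1.21 by the sum), Cnn1 (−1.35) and Myh11 (−1.08). Extracellular matrix and basal lamina genes had a median of −0.24, with 3 of 27 lower and 1 higher. Sparc was 3.23-fold lower (3.17 to 3.30) and Fn1, the fibronectin gene, 2.32-fold lower (2.21 to 2.43). Postn was −1.06 by its main row and −0.29 by the sum, and the basement membrane collagen gene Col15a1 was 2.75-fold higher (2.69 to 2.81). The progenitor, tendon and matrix medians lay below each of the 10000 random lists. For glial markers no direction could be read: the median was 0.18 (interval −0.64 to 0.33; percentile 86.5; −0.05 under library totals). Of 11 members, 8 were above 0, 0 were 2-fold apart, and values ran from −0.65 to 0.42. The glial interval includes the progenitor and mural medians (−0.48 and −0.40), so a shift of their size is not excluded. The potassium channel gene Kcna1 had a log2 ratio of −0.20.

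**Figure D2:**
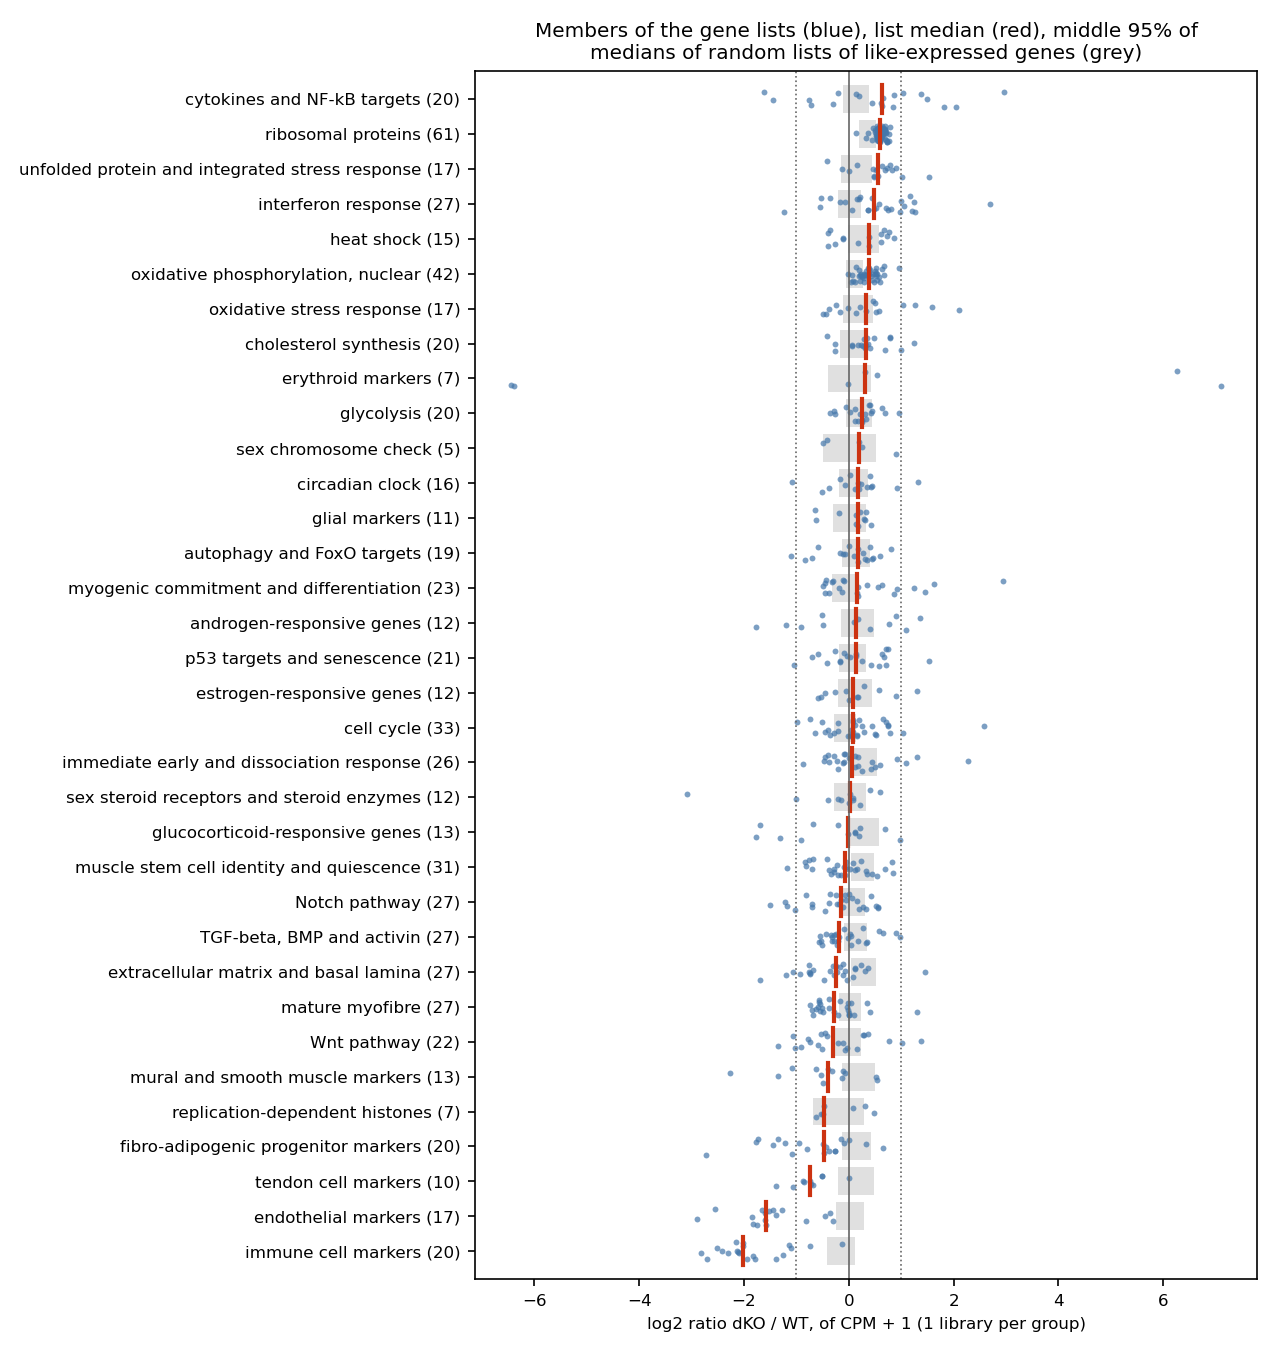
Points are the log2 ratios of dKO to WT of the measured members of each gene list (number in brackets), red bars are list medians and grey boxes span the middle 95% of medians of random lists of like-expressed genes. Immune and endothelial medians (−2.02 and −1.59) lie farthest to the left, and the median of cytokine genes (0.62) is to the right of its grey box.

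Genes of protein synthesis and respiration were higher by small amounts before the trend removal. All 61 ribosomal protein genes were above 0, none by 2-fold, with a median of 0.59 (percentile 99.98). Rplp0 was 1.53-fold and Rpl4 1.49-fold higher. Of 42 nuclear oxidative phosphorylation genes, 41 were above 0 and 0 were 2-fold apart, with a median of 0.38 (percentile 99.95) and values of 0.62 for Atp5b and 0.38 for Atp5a1, subunits of ATP synthase. After removal of the trend on abundance, length and GC content, chosen after seeing the data, the ribosomal median was −0.02 and the respiratory one 0.03. This removal cannot tell a shared rise of abundant genes from a technical trend, since such genes also enter the fit. Short and abundant transcripts were higher in dKO as a whole: among genes with 1 row and at least 100 counts, the shortest eighth (66 to 1247 bases) had a median log2 ratio of 0.21 and the longest (5764 to 83437 bases) one of −0.16. By abundance, the medians ran from −0.28 in the lowest eighth to 0.32 in the highest. The 13 genes of the mitochondrial genome had 0 measured members and were not analysed here.

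Cholesterol synthesis genes had a median of 0.32 (percentile 97.6), with 17 of 20 above 0, 1 higher by 2-fold and 0 lower. The member past 2-fold was squalene epoxidase, Sqle (2.41-fold, 2.28 to 2.54; named after its value was seen), and the abundant Srebf2, a regulator of the pathway, had a value of 0.49. Glycolysis genes had a median of 0.24 (percentile 65.1; 0.0020 under library totals and −0.02 with the trend removed) and 0 of 20 were 2-fold apart, with values of 0.63 for Pkm and 0.22 for Aldoa. TGF-beta, BMP and activin genes had a median of −0.19 (percentile 0.28) and 0 of 27 2-fold apart, with values of −0.34 for the co-receptor gene Tgfbr3 and 0.17 for Id3. Wnt pathway genes had a median of −0.31 (percentile 1.45), with 3 of 22 lower and 2 higher. The Wnt agonist gene Rspo1 (4.59-fold, 3.09 to 7.01), the receptor gene Fzd7 (2.12-fold; log2 ratio −1.07) and Dkk3 (2.22-fold, 1.89 to 2.60) were lower, and Lgr5, with 2 and 70 counts, was 34.7-fold higher (9.25 to 292). Of the 7 measured replication-dependent histone genes, 0 were 2-fold apart (median −0.47, percentile 9.96), with values of −0.47 for H2bc4 and −0.53 for H1f2. The 5 genes of the sex chromosome check had a median of 0.20 (percentile 75.1; −0.03 under library totals). Y-linked Ddx3y (6439 and 12191 counts) and Eif2s3y (1924 and 2323) were present in both libraries and Xist, which coats the inactive X of females, had 21 and 6 counts.

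The most extreme ratios belonged to single transcript rows, many of which did not carry over to the gene. The 12 highest were Hbb-bs, Hba-a1, Speg, Plac9a, Kif21a, Sap18b, C1rb, Nek1, Lrrc49, Pla2g6, Ak4 and Agtpbp1, and 6 of them were under 2-fold by the sum of rows. Speg, a muscle kinase gene, had 29 and 4111 counts by row but 4073 and 4525 by sum. The 12 lowest were Tns1, Ly6e, Hbb-b1, Hba-a2, Ralgapb, Dab2ip, Resf1, Cyld, Ptpru, Cep250, Svil and Eno1b, and 7 of them were under 2-fold by sum. The tensin gene Tns1 was at least 3482-fold lower by row (10352 and 0 counts) and 2.81-fold lower by sum (2.70 to 2.91). Others had near-identical copies with opposite ratios. Hba-a1 had 76 counts in WT and 11070 in dKO over its rows, and Hba-a2 had 6865 and 10. Summed, the alpha-globin genes were 1.60-fold higher (1.55 to 1.64) and the adult beta-globin genes 1.53-fold higher (1.48 to 1.58). The erythroid list therefore held 2 higher and 2 lower of 7 measured members around a median of 0.32 (percentile 91.9). The remaining copy families, chosen after their values were seen, gave dKO to WT ratios of 0.965 for Plac9, 1.24 for Sap18, 1.15 for Eno1, 1.37 for C1r and 0.852 for Il11ra. In Eno1, C1r and Il11ra 1 copy held most of the reads.

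**Figure D3:**
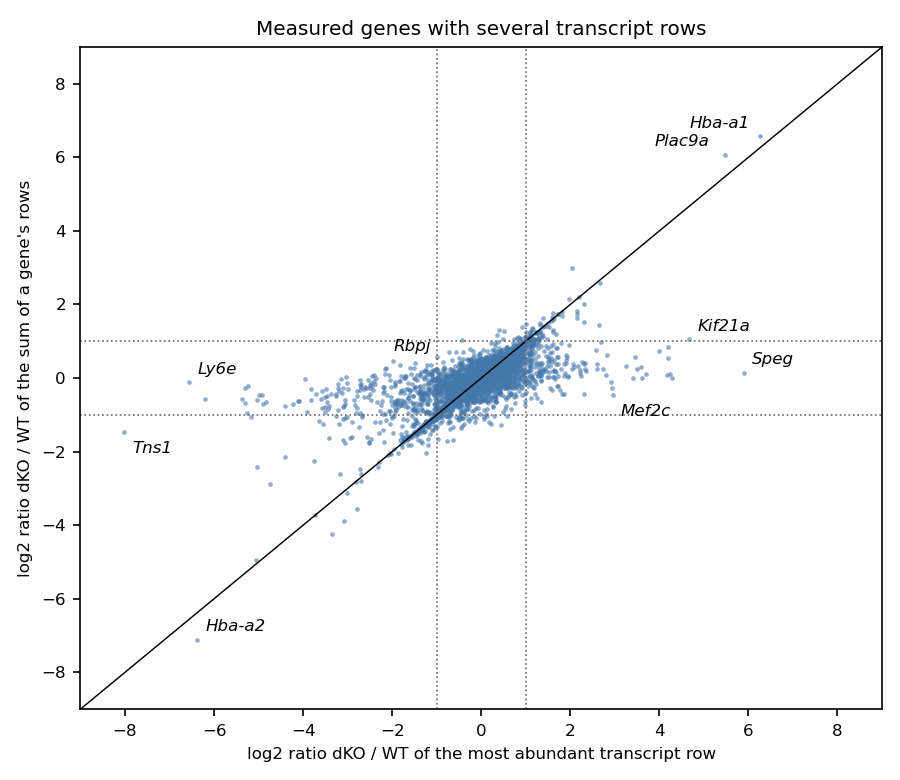
Each point is a measured gene with several transcript rows, with the log2 ratio of dKO to WT of its most abundant row on the x axis and of the sum of its rows on the y axis; dotted lines mark 2-fold. Points along the horizontal band are far apart by row and close by sum, such as Speg with 4073 and 4525 counts by sum.

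To set aside this division among rows, genes were also ranked by the sum of their rows, a ranking chosen after seeing the data, with at least 1000 counts in the higher library and without the copy families. Highest in dKO were Lif (8.22-fold, 7.66 to 8.83), the sialidase gene Neu2 (6.52-fold) and the chemokine gene Cxcl3 (6.44-fold, 5.50 to 7.59). They were followed by Fosl1, Rab6b, Asb5 (4.48-fold; 14105 and 63225 counts), the neurotrophic factor gene Gdnf (4.51-fold, 4.25 to 4.80), Nfkb1 (4.39-fold; 18312 and 80464 counts), Srxn1, Ino80d, the thyroid hormone activating enzyme gene Dio2 (3.84-fold), Adamts9, Tcim, Ccl11 and Erh. Lowest were the nuclear non-coding RNA Neat1 (9.20-fold, 8.44 to 10.0; 5296 and 576 counts), the transcription factor gene Pou2f1 (8.21-fold), Aak1 (6.46-fold), Ly6a and Loxl4. Further down were Cd93, Eppk1, H2-Aa, Plvap, Cd36, H2-Ab1, Vwf, Adgrl4 and Pid1, and several of these are known endothelial (Cd93, Plvap, Vwf, Adgrl4) or antigen presentation genes (H2-Aa, H2-Ab1).

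The most abundant transcripts were largely shared. Elongation factor Eef1a1 led both libraries (360563 and 473233 counts), and Egr1, Gpx3, Eef2 and Junb were also among the 10 most abundant in each. Hspa1b, Mt2, Zfp36 and Hspa1a were in that group only in WT. Flnc, Hspa8, Erfe and Sdc4 were in it only in dKO. Of these genes, Flnc, the gene of the muscle filamin, was 2-fold apart, at 3.09-fold higher in dKO (81547 and 254353 counts; 3.07 to 3.12).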

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

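Genes with 1 row only, the rule met by both row and sum, and the trend removal were chosen after seeing the data. No paired analysis was possible because the labels give no shared replicate numbers and each group has 1 library, and leaving out a library was not possible. The file holds no fold change of the authors, so a comparison with it was not run. Of 340 list medians under the alternatives, 319 stayed within the main 95% interval of the median and 23 had another sign.

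Genes higher in dKO numbered 260 with library totals, 914 and 237 with pseudocounts of 0.1 and 5, 286 by the sum of rows, 179 with 1 row only, 1604 and 67 under 1.5-fold and 4-fold rules, and 263 by both row and sum. Lower genes numbered 1934 and 329 with those pseudocounts, 390 with 1 row only, 2257 and 186 under the 1.5-fold and 4-fold rules, and 591 by both. A pseudocount of 5 shrinks all ratios by construction.

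Library totals alone move all ratios down. The medians became −0.31 for stem cell identity, −0.0847 for cell cycle, −1.83 for endothelial, −2.18 for immune, 0.14 for oxidative phosphorylation, 0.35 for ribosomal, −0.43 for TGF-beta, 0.0878 for cholesterol, 0.0020 for glycolysis, 0.31 for unfolded protein response and −0.67 for histone genes. With the trend removed they were −0.37 for stem cell identity, −0.36 for immediate early, 0.0266 for oxidative phosphorylation, −0.0205 for ribosomal, −0.0212 for glycolysis and 0.21 for unfolded protein response genes. The endothelial median was −1.20 with a pseudocount of 5, and the immune one −2.68 with 0.1 and −1.04 with 5. A floor of 100 counts gave 0.75 for myogenic genes, with fewer members measured. Of 147 named genes tested, the sum of rows reversed Rbpj to 0.28, Mef2c to −0.46 and Per3 to 0.0112, by counting rows that the main value leaves out. For the other shifts the cause was not tested. Depth was not varied, and with the pseudocount of 1 a gene under 1 CPM in both libraries cannot be 2-fold apart.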

Other observations

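The gene groups in the first 2 paragraphs, and every test below except those on the second endothelial list and on all 18 genes of the second immune list, were chosen after the results were seen. Ribosome biogenesis genes were higher in the dKO library, with a median log2 ratio of 0.76, at or above each of 10000 random lists of like-expressed genes. Of 22 members, 19 were above 0, 5 were higher by 2-fold and 0 lower. Rrs1 (2.41-fold, 2.26 to 2.56), Wdr43 (2.24-fold), the methyltransferase gene Fbl (2.20-fold) and the helicase gene Ddx21 (2.10-fold) were among them, and the median was 0.41 after removal of the trend on abundance, length and GC content. Aminoacyl-tRNA synthetase genes had a median of 0.34 (percentile 97.7; 0.28 after the trend), with 2 of 20 higher: Cars (log2 ratio 2.15, and 1.63 by the sum of rows) and Eprs (1.07). Proteasome genes had 26 of 27 above 0 and a median of 0.29 (percentile 95.7), which was −0.04 after the trend. Polyamine metabolism genes had a median of 0.34 (percentile 90.9; 0.07 after the trend), with Odc1 higher and Azin1 lower by row (−1.04, and −0.29 by sum).

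Growth factor genes of muscle injury had 6 of 18 higher by 2-fold and 1 lower by row, with a median of 0.22 (percentile 97.2; 0.14 after the trend). Lif, Gdnf (4.04-fold, 3.79 to 4.31 by row), Bdnf (2.18-fold), Csf3 (2.89-fold, 2.40 to 3.51) and Csf2 (0 and 81 counts) were higher, Vegfa was 1.70 by row and 0.82 by sum, and Hgf was −2.50 by row and −0.20 by sum. Among 13 long non-coding RNAs, with a median of 0.34 (percentile 91.4; −0.03 after the trend), Neat1 had a log2 ratio of −3.03 while Malat1, its nuclear neighbour on the chromosome, had −0.05. Meg3 (1.14, and 0.89 by sum) and Mirg (1.22), which share an imprinted locus, were higher. Focal adhesion genes went both ways (median 0.17, percentile 23.3; −0.04 after the trend), with Flnc higher (1.63), Actn1 (−1.80) lower, and Zyx at 1.52 by row and 0.45 by sum. Actin and SRF target genes had a median of 0.14 (percentile 27.1; −0.08 after the trend) and EGFR ligand and MAPK feedback genes one of 0.08 (percentile 52.7; 0.10 after the trend).

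Endothelial and immune markers were lower in dKO, although the sort excluded cells with CD31, CD45 and Sca1 in both groups, and none of the genes on these lists is on another fixed list. A trend with length, abundance or GC content is argued against, since the higher of the 2 medians was still −1.47 after its removal. A larger share of stem cells that dilutes all other types alike is argued against by the glial median, which lay 2.20 above the immune one. The glial interval (−0.64 to 0.33) lay above the immune (−2.15 to −1.39) and endothelial (−1.75 to −1.28) intervals. These intervals describe the spread of member genes within 1 pair of libraries, not between animals. The glial interval does not exclude a smaller dilution shared by all types. Fewer endothelial cells passing the sort may account for the endothelial part: a second list of 16 genes had a median of −1.29 (−1.51 to −0.95), with all below 0. Abundant markers such as Fabp4 (228 and 75.3 CPM) and Aqp1 (214 and 63.0 CPM) went the same way. Both belong to the first endothelial list, so they add no separate support. Fewer immune cells may account for the immune part. Over all 18 genes of a second list the median was −0.96, short of the −1 that the test asked for. A filter set after the values were seen kept the 13 genes that can reach −1 with the pseudocount. Their median was −1.31 (−1.58 to −0.83). Lyz2 (75.3 and 30.8 CPM) and Cd74 (50.8 and 13.7 CPM) were lower too, but belong to the first immune list and add no separate support. An effect of genotype on these cell types, in number or in RNA per cell, stays open and untested, since genotype and library coincide.

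Large ratios of single rows were frequent: 3.95% of measured genes with several rows were at least 4-fold apart, against 0.532% of those with 1 row. Reads divided differently among the rows of a gene could account for most of them, since 69.2% of 201 such genes were under 2-fold apart by the sum. Reads divided among near-identical copies could account for the globin, Plac9 and Sap18 ratios, since these families were under 2-fold apart when summed. That held for 7 of 7 copy families, but families beyond the globins were chosen after their values were seen, so the count is weak support. The test says little for Eno1, C1r and Il11ra, where the other copy holds most of the reads. A real difference in isoform use with genotype was not tested and stays open for genes such as Mef2c, Rbpj and Tns1.

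Members of the cytokine, oxidative stress, immediate early and myogenic lists were higher in dKO, 15 of them past 2-fold by both row and sum, while others on these lists were lower and of the list medians only the cytokine one (0.62) lay above its random range. RNA of immune or endothelial cells as the source is argued against by the lower markers of both types, the higher of whose medians was −1.59. A trend with length, abundance or GC content cannot be judged from these 15 members, since they were chosen for their size. Their median was 1.48 before and 1.26 (0.97 to 1.73) after its removal. After removal, 11 were still past 2-fold, and Cxcl1, Ier5, Gclm and Myc were not. The median of the whole cytokine list fell from 0.62 to 0.24, a little above random lists (−0.21 to 0.21). For that list only, this argues against the trend as the whole cause. A longer or harsher isolation of the dKO cells could raise stress genes, but the immediate early median was 0.0590, under its random range, and −0.36 after the trend. The heat shock median of 0.38 was within its range and −0.02 after the trend. Such an isolation effect cannot be told apart from other causes with 1 library per group. An effect of the dKO genotype on stem cell activation stays open and untested. Myod1 was higher and Pax7 lower, and the stem cell identity and Notch lists stood low among like-expressed genes (percentiles 0.15 and 1.57). Yet 30 of 31 identity and 23 of 27 Notch genes were not 2-fold apart, and which cells the Notch RNA came from was not tested. The immediate early list was low for its abundance, and Rbpj was −1.51 by its main row but 0.28 by the sum of its rows. Deciding the question needs replicate libraries of each genotype.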
